A study of Homo sapiens with 3 samples.

How the data were processed

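Total RNA of KYSE140 cells, a line from human esophageal squamous cell carcinoma, was extracted after siRNA transfection and libraries were made by Illumina protocols, per the labels. The labels give 1 negative control sample and 2 samples with DLX5 siRNA, numbered 1 and 2. The series' design text speaks of retinal RNA, in triplicate, which the sample labels do not bear out, and the sample labels were followed.

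The authors deposited 1 table of genes. Per the file headers, the authors' values are FPKM, given in 2 replicate columns and as their mean for each sample; the control's mean equals that of its replicate columns in every gene up to rounding. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, a DESeq entry of version 3.4 and the genome build hg19, without roles or order. The deposited table also gives the authors' log2 fold changes between samples and, per the file headers, p-values and DEGseq q-values for them. FPKM is already divided by transcript length and depth, so a gene that takes a larger share of the reads lowers all others, and values of genes with few reads are coarse. The strand setting of the library and of the counting is not given in the sources used here.

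Of 19280 lines, 14 without a gene ID (spilled annotation text) and 2047 genes with no value in any sample were left out, and 17219 genes remained. Of their Entrez IDs, 17182 matched a reference table of gene names, which also restored 26 symbols that a spreadsheet had turned into dates. Of the columns with values per sample, 2 carry the same heading and were not used; where replicate column 1 of a siRNA sample was needed, it was taken as 2 times the sample mean minus replicate column 2. Coordinates are those of the table. Sequence comparisons used GENCODE v29 transcripts, which belong to another genome build, for sequence only.

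The number of reads behind the FPKM values is not in the table. It was estimated at 16950000 to 17500000 per replicate column from the spacing of low values of short genes with a single transcript, taking the lowest depth that fits, a rule set after a doubled depth came out in some columns. Replicate columns of a sample differed by a median of 2.23% to 3.96% for genes with over 3000 estimated reads and by 12.9% to 14.7% for genes with 30 to 100, and their variance was 1.07 to 10.4 times that of read counting. They are thus not copies of each other, but they carry no label of their own and were counted as 1 value per sample. The p-values of the main gene test measure the spread between the 2 siRNA samples, which may be technical and includes any difference between the siRNAs. With the replicate columns as separate values they measure the spread within samples. The p-values of gene lists, words and pathways compare sets of genes with other genes, which are not independent samples.

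The planned test was for counts. As the table holds FPKM, the fallback fixed beforehand was used: limma 3.58.1 in R 4.3.3 with a trend, on log2(FPKM + 1), for the 12078 genes with at least 1 FPKM in at least 1 of the 3 samples, control (1 sample) against DLX5 siRNA (2 samples), Benjamini-Hochberg 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; ratios given as fold are of FPKM itself. The moderated spread had 5.16 prior degrees of freedom beside 1 residual degree of freedom. A planned Poisson interval for the DLX5 ratio needs counts and was not made. The pipeline was tested on simulated data: over 20 runs with 200 changed among 12078 genes, 48.0% of genes changed by 1 on the log2 scale and 98.5% of those changed by 2 were found, with 8.3% false calls and 0 of the wrong sign. Noise was drawn from the fitted spread, alike for control and knockdowns. Changes were placed only in genes with a mean log2(FPKM + 1) above 2. The simulation thus says nothing of lower genes or of a control out of place.

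Genes at least 2-fold changed with both siRNAs were counted by size alone. Agreement of the siRNAs was set beside 100 simulated sets of unchanged samples against 1 control, drawn from the differences between the siRNA samples within bins of expression. Gene lists were tested with camera in limma, with a preset correlation of 0.01 and with an estimated correlation, and their medians were ranked among 10000 random lists matched on mean expression. The list of mitochondrially encoded genes had no tested member.

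Genes were named by a rule fixed before the data were examined: the DLX genes, then the 12 lower and 12 higher genes past the test with a mean of at least 1 FPKM and the same direction in both siRNA samples, ranked by the smaller of the changes, then up to 4 members of each list ranked likewise. Not all of these genes are given in the text. Genes named outside the rule are marked as such.

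Alternatives fixed beforehand were a pseudocount of 0.1, no filter, an adjusted p under 0.10, other minimum means, an estimated correlation, and leaving out each siRNA sample. Added after seeing the data were the 6 replicate columns as separate values, scaling by the median ratio to the control, quantile normalization, no trend, the DLX list without DLX5, a pseudocount of 0.1 for the correlation of the siRNAs, and leaving out genes that carry enriched words of 7 bases. These words were searched in the longest annotated 3' UTR of each gene within deciles of its length, with 1000 permutations of the gene sets (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3); 11993 tested genes had a 3' UTR, 99.3% of them. A word planted in simulated gene sets was ranked first.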

Results

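RNA sequencing was used to measure gene expression in KYSE140, an established cell line from a human esophageal squamous cell carcinoma, after transfection with siRNA against DLX5. DLX5 encodes a homeobox transcription factor of the distal-less family, best known from skeletal and craniofacial development. The table held 1 negative control sample and 2 knockdown samples, called siRNA1 and siRNA2 after the labels' numbering of the knockdowns. Each sample had 2 replicate columns of FPKM (fragments scaled to transcript length and sequencing depth), and n = 1 value per sample, their mean, entered each comparison. An SD below is the spread over the 2 replicate columns of a sample, which may be technical; nothing in the labels says that they came from separate cultures. The steps between low FPKM values of short genes gave an estimated depth of 16950000 to 17500000 reads per replicate column, with 85.1% to 95.9% of such values within 0.2 reads of a whole number at the fitted depth, against 49.0% to 49.7% on average and at most 60.2% when the depth was fitted in the same way to permuted transcript lengths.

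The first comparison asked whether the targeted gene was lower in the samples labelled as knockdowns. DLX5 (Entrez gene 1749, chromosome 7, 96649702 to 96654143, minus strand, hg19) stood at 13.0 ± 0.0990 FPKM in the control, at 3.63 ± 0.0283 with siRNA1 and at 3.25 ± 0.0283 with siRNA2 (SD over replicate columns). It was thus 3.58-fold lower with siRNA1 and 4.0-fold lower with siRNA2, and its log2 fold change of -1.66 ± 0.18 (SE) passed the test across all genes (limma, adjusted p = 0.0210). That call is lost without the filter on low FPKM (adjusted p = 0.320) and with quantile normalization (adjusted p = 0.0531), at log2 fold changes of -1.66 and -1.63. Transcripts of other DLX genes were also lower. DLX3, a regulator of epidermal differentiation, went from 2.58 FPKM to 0.390 and 0.535 (adjusted p = 0.0259), and DLX2 from 2.82 FPKM to 0.820 and 0.910 (adjusted p = 0.0381). DLX1 read 5.38 FPKM in the control against 2.56 and 2.97 and did not pass (adjusted p = 0.0899). DLX6, the neighbor of DLX5, read 9.75 FPKM against 7.89 and 9.45 (adjusted p = 0.709), and DLX4 read 7.06 FPKM against 6.51 and 6.47 (adjusted p = 0.792). No stretch of 31 bases is shared between DLX5 transcripts and those of the other 5 genes, and the longest shared stretch, 20 bases, is with DLX3.

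**Figure D1:**
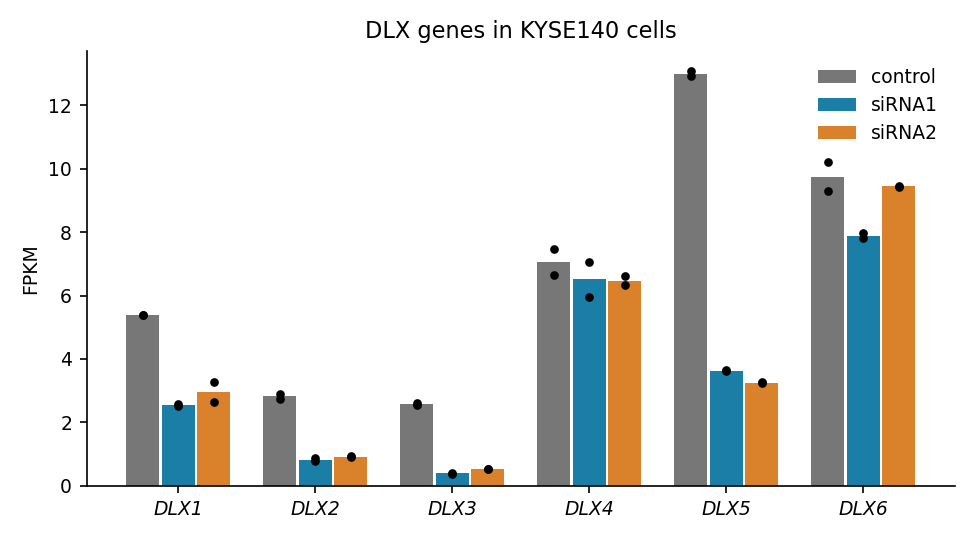
FPKM (linear axis from 0) of the 6 DLX genes in the control, siRNA1 and siRNA2 samples of KYSE140; bars are sample means and dots the 2 replicate columns. DLX5 stands at 13.0 FPKM in the control and at 3.63 and 3.25 with the siRNAs; DLX2 and DLX3 are lower as well, while DLX4 and DLX6 are not called.

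The main comparison asked which genes differed between the control and the DLX5 siRNA samples. Of 12078 genes tested, 171 rose and 202 fell in the DLX5 siRNA samples relative to the control at a Benjamini-Hochberg adjusted p under 0.05 (limma with a trend of the spread on expression). All 373 moved the same way in both siRNA samples, but the test fixes this. Its spread is the difference between the siRNA samples, so a gene that moved in opposite ways could not pass. At an unadjusted p under 0.05 there were 2359 genes. By size alone, 95 genes were at least 2-fold higher and 141 at least 2-fold lower with both siRNAs on the log2(FPKM + 1) scale, of 11801 genes with a mean of at least 1 FPKM. Counted with siRNA1 alone, 288 genes were at least 2-fold lower, and with siRNA2 alone 226. With a pseudocount of 0.1 in place of 1, 212 were at least 2-fold lower with both, and 91 with a mean of at least 5 FPKM. These calls rest on 1 residual degree of freedom per gene and on 1 control assumed to vary like the knockdowns, and they depended on the setting. Without the filter on low FPKM no gene passed (2444 at an unadjusted p under 0.05), and after quantile normalization 12 rose and 10 fell. With the 6 replicate columns as separate values 2638 rose and 2247 fell with both siRNAs. At that setting, whose spread is within samples, 4883 genes also differed between the siRNAs. Without the genes that carry the word UCGGAGA in a coding transcript, a set chosen after seeing the data, 10525 genes were tested, of which 106 rose and 189 fell.

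Of the genes that fell most, PLAU, the urokinase plasminogen activator, went from 39.3 ± 1.87 FPKM to 3.89 ± 0.0283 and 4.38 ± 0.177, that is 10.1-fold lower with siRNA1 and 8.99-fold lower with siRNA2 (log2 fold change -2.98 ± 0.17, adjusted p = 0.0137). SERPINB2, the plasminogen activator inhibitor of the same system, fell from 7.37 FPKM to 0.365 and 0.600. KRT16 fell from 20.4 FPKM to 3.59 and 3.73, KRT14 from 461 FPKM to 99.0 and 113, and KRT80 from 51.8 FPKM to 14.8 and 9.84. The interleukin-1 receptor antagonist IL1RN fell from 5.04 FPKM to 0.470 and 0.655, and the fibroblast growth factor binding protein FGFBP1 from 92.3 FPKM to 21.2 and 26. The deacetylase SIRT1 fell from 11.2 FPKM to 2.56 and 2.10, GPRC5A from 11 FPKM to 1.40 and 2.59, the ganglioside synthase ST3GAL5 from 11.5 FPKM to 2.76 and 2.07, and the stress gene GADD45B from 22.7 FPKM to 4.80 and 6.21. The adjusted p of these genes lay between 0.0137 and 0.0246. Keratins have near-identical copies and pseudogenes whose reads can be split, so the level of any single keratin is uncertain.

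The genes that rose most were of mixed function. TPM4, a tropomyosin of the actin cytoskeleton, rose from 61.1 ± 0.389 FPKM to 400.0 ± 3.09 and 335 ± 6.26 (log2 fold change 2.56 ± 0.15, adjusted p = 0.0137). TOMM22, a receptor for protein import into mitochondria, rose from 19.2 FPKM to 76.2 and 75.1. EMC6, a subunit of the endoplasmic reticulum membrane complex, rose from 18.3 FPKM to 72.6 and 69.2, and GANAB, a glucosidase of glycoprotein folding, from 49.4 FPKM to 173 and 166. OGFR rose from 4.58 FPKM to 19.7 and 20.4, HDGFRP2 from 9.58 FPKM to 37.5 and 34.3, and R3HCC1 from 5.14 FPKM to 22.1 and 18.6. The extracellular sulfatase SULF1 rose from 7.32 FPKM to 26.4 and 38.5, the transcription factor SOX21 from 6.13 FPKM to 22.7 and 22.0, and the oxysterol receptor GPR183 from 0.465 FPKM to 7.14 and 4.10. SULT1A3, listed at 0 in the control and at 2.53 ± 3.57 and 2.48 ± 3.50 FPKM with the siRNAs, has a near-identical copy and is uncertain. The word UCGGAGA occurs in the 3' UTR of TPM4 alone among the 12 higher genes that the naming rule takes, and somewhere in a coding transcript of 6 of the 12, a property of the called genes that is examined in the closing section.

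**Figure D2:**
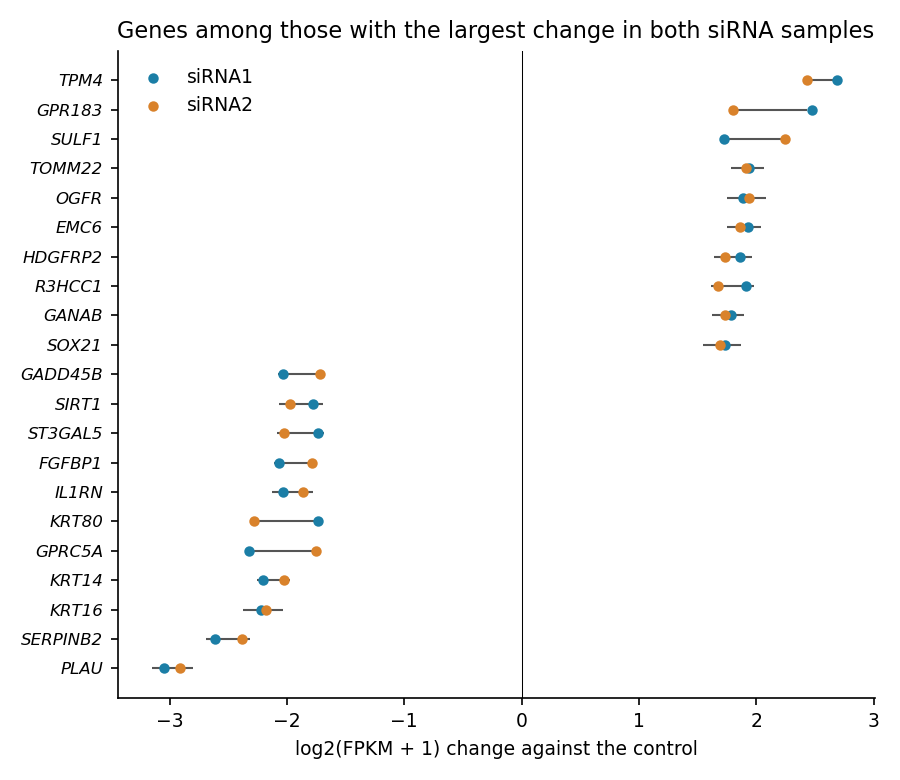
Change in log2(FPKM + 1) against the control with siRNA1 and siRNA2 (colored dots) for genes among those that fell or rose most in both, without SULT1A3, with bars of ± 1 SE around the fitted change. PLAU lies at -3.04 and -2.91, and TPM4 at 2.69 and 2.43.

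Gene lists fixed before the data were examined were then compared with all other genes (camera, preset correlation of 0.01). Of 36 lists with a tested member, 21 were lower and 4 higher at an adjusted p under 0.05. A list result covers tested members only, and lists differed in how many were tested. These were 24 of 24 basal keratinocyte and adhesion genes but 21 of 38 squamous differentiation genes and 10 of 28 glandular epithelium markers. For fibroblast markers they were 6 of 18 and for neuroendocrine markers 5 of 13. With a correlation estimated from the data, which here rests on 1 residual degree of freedom, no list passed and the smallest adjusted p was 0.498, shared by 27 lists. Those 27 lists include NF-kB and cytokine genes (camera adjusted p = 1.66e-11 with the preset correlation) and retinal markers (0.166). With 1 residual degree of freedom this test can hardly pass any list, so it neither backs nor counts against one. The list results therefore rest on the preset correlation alone, which these samples cannot check.

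Lists of squamous and keratinocyte genes were lower than other genes with the preset correlation, with part of their members called. Of 21 tested genes of squamous differentiation, 8 fell and none rose (14 fell when adjusted over the list alone), and the median log2 fold change was -0.93 with siRNA1 and -0.62 with siRNA2, below all of 10000 random lists matched on expression (camera adjusted p = 8.16e-09). They included KRT13, a keratin of the esophageal lining, which fell from 51.3 FPKM to 13.9 and 18.2, the cornified envelope gene SPRR1B, which fell from 16.6 FPKM to 4.66 and 4.93, and KRT6B, which holds ACUCAGU, the word most enriched among the lower genes, in its 3' UTR and fell from 18.5 FPKM to 4.20 and 5.93. Of 24 genes of basal keratinocytes and adhesion, 5 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 9.15e-09). KRT5 fell from 3127 FPKM to 1228 and 1274, KRT17 from 3057 FPKM to 947 and 738, and SFN from 708 FPKM to 332 and 333, while the hemidesmosomal collagen COL17A1, named after its values were seen, rose from 126 FPKM to 227 and 258. Among 25 squamous transcription factors 4 fell and 1 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.00312). The regulators of keratinocyte differentiation GRHL3 and ZNF750 fell from 19.9 FPKM to 7.85 and 5.98 and from 1.53 FPKM to 0.220 and 0.320, BNC1 from 7.75 FPKM to 2.97 and 3.49, and FOXE1 from 61.2 FPKM to 28.9 and 31.7. PITX1, again named after its values were seen, rose from 18.6 FPKM to 35.1 and 39.7. TP63, a master regulator of squamous epithelium named outside the rule because the series' title names it, read 92.1 FPKM against 90.6 and 79.4 and did not pass (adjusted p = 0.727). Of 22 reported TP63 targets 3 fell (KRT14, EGFR and DLX3) and 2 rose, COL17A1 and PERP, the latter also named after its values were seen (11 and 3 adjusted over the list alone; camera adjusted p = 0.00552). For these 4 lists the adjusted p was 0.498 with an estimated correlation.

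Inflammatory genes gave the smallest p of any list. Of 23 tested NF-kB and cytokine genes, 10 fell and none rose (15 fell when adjusted over the list alone), with a median log2 fold change of -0.82 with siRNA1 and -0.80 with siRNA2 (camera adjusted p = 1.66e-11). Interleukin-1 beta, IL1B, fell from 5.03 FPKM to 0.970 and 0.795, IL23A from 13.2 FPKM to 4.04 and 3.81, and the adaptor TRAF1 from 2.48 FPKM to 0.270 and 0.290. Of 30 NRF2 targets 3 fell and 1 rose (camera adjusted p = 3.78e-04): the heme oxygenase HMOX1 fell from 6.75 FPKM to 2.30 and 2.70, the transporter ABCC3 from 12.9 FPKM to 3.39 and 4.71, and TRIM16 from 70.8 FPKM to 33.2 and 32.6, while ME1, named after its values were seen, rose from 12 FPKM to 23.6 and 24.5. Of 27 p53 targets 2 fell (camera adjusted p = 0.00312). The cell cycle inhibitor CDKN1A fell from 63.1 FPKM to 22.7 and 16.7, and GADD45A from 114 FPKM to 41.7 and 47.8. Adjusted over the list alone, 8 fell and 2 rose among NRF2 targets and 5 fell and 1 rose among p53 targets. The adjusted p of all 3 lists was 0.498 with an estimated correlation.

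The lists of growth factor feedback, YAP and TEAD targets, mesenchymal genes, epithelial junctions and glandular markers were lower with the preset correlation, with few of their members called. Among 28 genes of growth factor and MAPK feedback, 3 fell, namely FGFBP1, EGFR, which went from 151 FPKM to 55.4 and 61.2, and the phosphatase DUSP4, from 5.75 FPKM to 1.37 and 1.94 (camera adjusted p = 4.43e-04, and adjusted p = 0.567 with an estimated correlation). Among 22 YAP and TEAD targets 3 fell, AXL, PTPN14 and NUAK2, and AMOTL1, named after its values were seen, rose (camera adjusted p = 2.51e-04). The receptor kinase AXL fell from 15.7 FPKM to 4.49 and 5.87. It was also 1 of 2 genes that fell, with TAGLN, among 25 mesenchymal genes (camera adjusted p = 9.44e-05). The tight junction genes CLDN4 and CLDN1 fell from 113 FPKM to 36.7 and 34.5 and from 29.4 FPKM to 9.02 and 9.39, the only 2 calls among 21 epithelial junction genes (camera adjusted p = 0.00394, and adjusted p = 0.50 with an estimated correlation). Without genes that hold either enriched word in the 3' UTR, CLDN1 among them, the median of the junction list went from -0.16 to -0.07 (adjusted p = 0.0385); with all its genes the median was -0.33 with siRNA1 and -0.08 with siRNA2. Of 10 glandular epithelium markers, KRT7, KRT19 and the transcription factor GATA6 fell (camera adjusted p = 7.13e-05), KRT19 from 169 FPKM to 71.8 and 77.2. The 3' UTRs of EGFR, AXL, PTPN14, CLDN1 and GATA6, and of ABCC3 among the NRF2 targets, hold ACUCAGU. The count adjusted over the list alone was 5 for growth factor feedback, 9 lower and 2 higher for YAP and TEAD targets, 5 for mesenchymal genes, 2 for junctions and 4 for glandular markers. YAP and TEAD targets, mesenchymal genes and glandular markers had an adjusted p = 0.498 with an estimated correlation.

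Lists of developmental signaling were lower as a whole with few calls of their own. In the WNT list 1 of 38 genes fell, the receptor ROR2, from 3.90 FPKM to 0.740 and 1.15 (camera adjusted p = 4.43e-04; 1 adjusted over the list alone). In the NOTCH list HES1 and HES2 fell of 20 genes (camera adjusted p = 0.00398; 2 adjusted over the list alone). BMP2 fell from 3.43 FPKM to 1.05 and 1.09 and was the only call among 26 genes of TGF-beta and BMP response (camera adjusted p = 0.00312; 8 adjusted over the list alone). FOXC2 and BMP2 fell among 16 osteogenic and craniofacial genes (camera adjusted p = 0.00522; 5 adjusted over the list alone). None of 8 reported DLX5 target genes passed the gene test, although the list was lower (camera adjusted p = 0.00312; 1 adjusted over the list alone): MYC read 69.5 FPKM against 26.8 and 47.8, and RUNX2 read 5.80 FPKM against 3.04 and 3.21. JUNB fell of 17 immediate early genes (camera adjusted p = 0.0231; 3 adjusted over the list alone), NDRG1, whose 3' UTR holds ACUCAGU as that of RUNX2 does, fell and PFKL, named after its values were seen, rose of 30 genes of glycolysis and hypoxia (camera adjusted p = 0.00395; 7 lower and 1 higher adjusted over the list alone), and the DLX genes themselves made up a list with 3 of 6 lower (camera adjusted p = 2.48e-04; 4 adjusted over the list alone). The DLX list holds the targeted gene; without DLX5, a test chosen after seeing the data, its median was -0.76 over 5 genes (camera adjusted p = 0.00280). The fibroblast list was lower with no call among 6 genes (camera adjusted p = 0.00406; 1 adjusted over the list alone). All of these lists had an adjusted p = 0.498 with an estimated correlation.

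Respiratory chain, neuroendocrine and cell cycle genes made up the 4 higher lists. Of 40 respiratory chain genes 2 rose, among them SDHB from 53.2 FPKM to 88.6 and 91.9 (camera adjusted p = 0.00112; 3 adjusted over the list alone), with list medians of 0.20 with siRNA1 and 0.12 with siRNA2. Of 5 tested neuroendocrine markers the granins SCG2 and CHGB rose, SCG2 from 12.7 FPKM to 34.0 and 38.4 and CHGB from 30.9 FPKM to 59.9 and 55.0 (camera adjusted p = 0.00944; 3 adjusted over the list alone). None of 40 genes of S phase and DNA replication passed (camera adjusted p = 0.00407; 2 higher and 1 lower adjusted over the list alone): E2F1 read 16.4 FPKM against 29.3 and 27.4. Among 40 genes of G2 and mitosis the survivin gene BIRC5 rose from 28.7 FPKM to 67.1 and 61.6 and the checkpoint gene MAD2L1, named after its values were seen, fell from 36.2 FPKM to 18.7 and 14.2 (camera adjusted p = 0.00406; 1 higher and 1 lower adjusted over the list alone). The G2 and mitosis list had an adjusted p = 0.567 with an estimated correlation and the other 3 lists had 0.498.

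The remaining 11 lists were not called. Their camera adjusted p was 0.933 for cholesterol synthesis, where PMVK rose (1 adjusted over the list alone), 0.827 for the unfolded protein and ATF4 response, 0.660 for endothelial markers, 0.478 for small interfering RNA machinery, 0.294 for HOX genes, where HOXC10 rose from 13.3 FPKM to 28.6 and 31.7 (3 adjusted over the list alone), and 0.171 for ribosomal proteins. It was 0.166 for both polycomb regulators and retinal markers, 0.128 for replication-dependent histones, and 0.121 for both the type I interferon response and immune cell markers. Adjusted over the list alone, 1 histone gene was higher, and 1 retinal and 1 immune cell marker were lower. AGO2 and TNRC6A, which carry out silencing by small RNAs, read 24.9 FPKM against 12.8 and 21.5 and 28.0 FPKM against 12 and 20.4, with neither passing; the 3' UTR of AGO2 holds ACUCAGU.

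**Figure D3:**
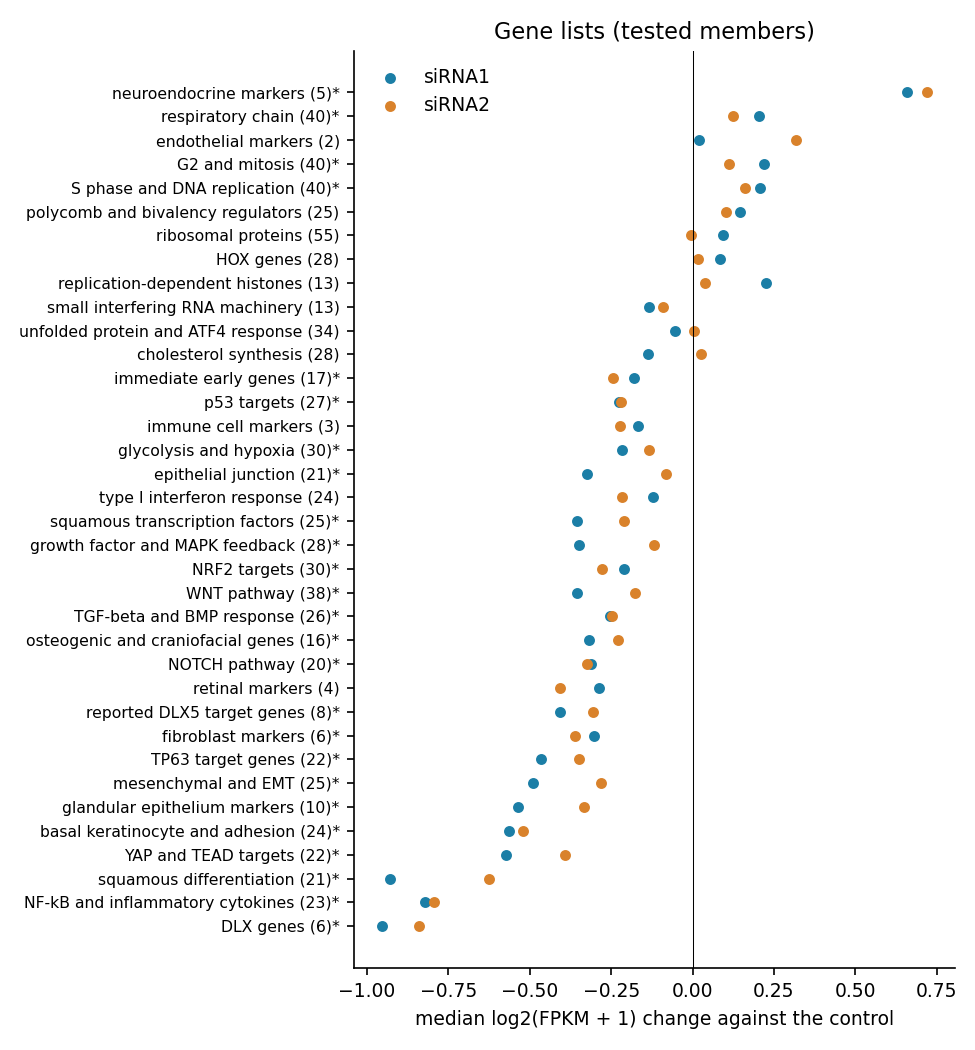
Median change in log2(FPKM + 1) against the control for the 36 gene lists with siRNA1 and siRNA2 (colored dots), with the number of tested members in parentheses and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The NF-kB and inflammatory cytokine list lies at -0.82 and -0.80, and the respiratory chain list at 0.20 and 0.12.

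Changes against the control were correlated between the siRNAs across genes, although 4883 genes differed between them with the replicate columns as separate values. The log2 fold changes against the control had a Pearson correlation of 0.800 and a Spearman correlation of 0.750 across 11801 genes, which are not independent replicates, and 77.2% of genes had the same sign. Both use the same control sample, so unchanged samples were simulated against 1 control: they gave 0.499, 0.476 and 66.6%. The covariance was 0.137 against 0.0349 simulated, a difference of 0.102. The 95 genes at least 2-fold higher and 141 at least 2-fold lower with both siRNAs (212 lower with a pseudocount of 0.1 and 91 with a mean of at least 5 FPKM) compare with 6.33 and 6.82 in the simulated samples, and with 1.42 and 5.52 for independent lists of the same lengths. The simulation gave the control the same spread as the siRNA samples, a spread that holds any difference between the siRNAs. That choice by itself fixes the simulated correlation and share of equal signs, so it cannot show how far this control lies out of place. The control is 1 sample, and its replicate columns were not set apart against each siRNA, so part or all of the excess may come from it.

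**Figure D4:**
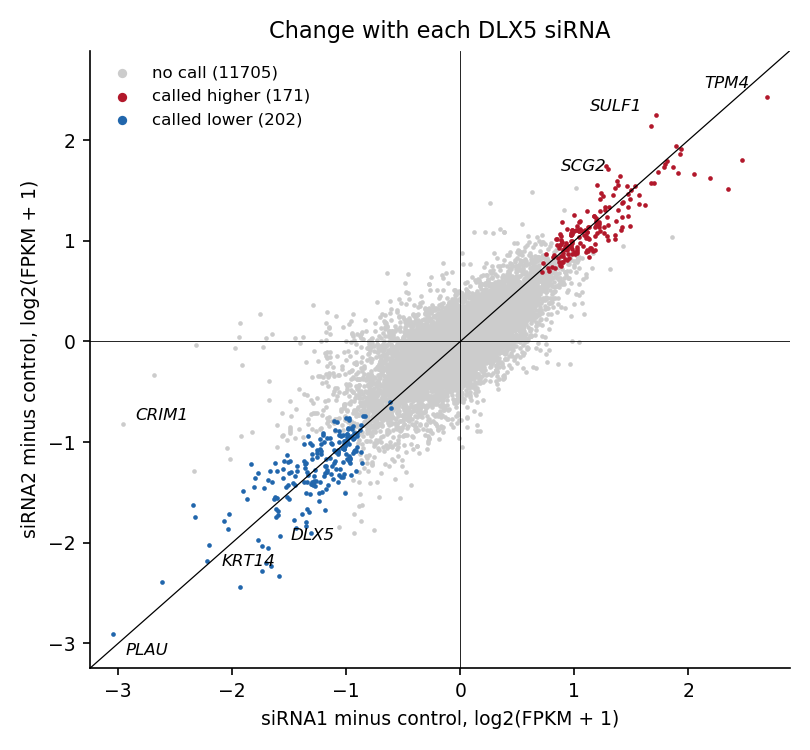
Change in log2(FPKM + 1) against the control with siRNA1 (horizontal) and siRNA2 (vertical) for 12078 genes, colored by call, with the line of equal change. The 171 higher and 202 lower calls lie near that line, which the test favors, since it takes its spread from the difference between the siRNAs. CRIM1, at -2.96 with siRNA1 and -0.82 with siRNA2, is not called.

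The siRNA samples were also set against each other by size, since each siRNA has 1 sample and allows no test between samples. With siRNA2, 47 genes were at least 2-fold higher and 8 at least 2-fold lower than with siRNA1. With a pseudocount of 0.1 these counts were 75 and 33, and with a mean of at least 5 FPKM they were 46 and 5. CRIM1, a regulator of bone morphogenetic proteins, read 31.9 FPKM in the control, 3.24 with siRNA1 and 17.6 with siRNA2. The genes furthest apart, named after their values were seen as was CDH1, were DDAH1 (25.8 FPKM in the control, 3.17 with siRNA1 and 20.3 with siRNA2) and TSPAN6 (19.9, 3.20 and 19.4 FPKM). E-cadherin, CDH1, read 123 FPKM in the control, 31.8 with siRNA1 and 104 with siRNA2.

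The authors' deposited table holds its own comparisons of the samples by DEGseq. At a q-value under 0.05, the authors list 5373 genes as higher and 4849 as lower with siRNA1 than in the control. For siRNA2 the deposited table has 4706 higher and 4606 lower, and for siRNA2 against siRNA1 3623 higher and 4469 lower. With a change of at least 2-fold in addition, the authors list 503 as higher and 870 as lower with siRNA1, 351 and 788 with siRNA2, and 201 and 292 with siRNA2 against siRNA1. The last pair has more lower than higher genes, the opposite of the 47 and 8 given above (75 and 33 with a pseudocount of 0.1); among genes with a mean of at least 1 FPKM it is 83 higher and 41 lower. The q-values in the authors' deposited table come from a comparison whose treatment of replicates is not given in the sources used here, and each sets 1 sample against another.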

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

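The replicate columns, the scalings, the pseudocount of 0.1 for the correlation of the siRNAs, the fit without a trend, the DLX list without DLX5 and the removal of word carriers were chosen after seeing the data. With no filter on low FPKM no gene was called higher (0) or lower (0), and the adjusted p of DLX5 was 0.320 at the same log2 fold change of -1.66; the prior degrees of freedom then fell from 5.16 to 1.46, and 2444 genes had an unadjusted p under 0.05. Quantile normalization left 12 higher and 10 lower genes, with 21 of the 373 main calls kept, and DLX5 at -1.63 (adjusted p = 0.0531); the median log2 change of the 171 higher genes was 1.08 before and after and their median SE 0.160 and 0.156, but the prior degrees of freedom fell to 3.85, which raises the p. An adjusted p under 0.10 gave 365 higher and 468 lower, and the 6 replicate columns gave 2638 and 2247, with 369 of the 373 kept, since the spread is then that within a sample. Without genes that carry UCGGAGA anywhere in a coding transcript, 106 rose. Under the other alternatives, 130 to 154 rose and 149 to 189 fell. Genes at least 2-fold lower with both siRNAs numbered 212 with a pseudocount of 0.1 and 91 with a mean of at least 5 FPKM, where fewer genes enter; leaving out either siRNA sample gave 226 to 288, and 122 to 137 for higher genes. Genes at least 2-fold apart between the siRNAs numbered 75 higher and 33 lower with siRNA2 at a pseudocount of 0.1, and 5 lower at a mean of at least 5 FPKM. With an estimated correlation, a test that can hardly pass any list at 1 residual degree of freedom, 0 lists were lower and 0 higher. Scaling and the removal of genes with either enriched word in the 3' UTR each gave 21 and 4. With that removal the epithelial junction median went from -0.16 to -0.07 (camera adjusted p from 0.00394 to 0.0385). Leaving out a siRNA sample allows fold changes but no test, and turned no called list around. Named genes other than the DLX genes could not turn, since they were chosen for the same direction in both siRNA samples. No DLX gene turned, and DLX5 then ranged from -1.72 to -1.60. The medians of 12 lists without siRNA1 and of 10 without siRNA2 moved by more than the spread between the siRNAs. The Pearson correlation of the siRNAs, 0.800, was 0.797 at a mean of at least 5 FPKM and 0.801 at a pseudocount of 0.1. The Spearman correlation, 0.750, was 0.756 and 0.746. Of 150 other named genes, 69 had a call and 81 had none to lose. All 69 lost it with no filter and 55 of the 69 with quantile normalization. A pseudocount of 0.1 took the call from 6, the fit without a trend from 3, scaling from 2 and the 6 replicate columns from 1. Without carriers of UCGGAGA in the 3' UTR, 145 named genes were left, called or not, and 2 lost their call. Without carriers of ACUCAGU there, 131 were left and 2 lost their call. No paired analysis was possible because 1 control sample serves both siRNA samples. The planned count-based fits (other size factors, other count tests, count filters and CPM) were not run, since the table holds FPKM. In simulations of this design, which left out changes in low genes and let the control vary like the knockdowns, a change of 1 on the log2 scale was found in 48.0% of cases. A gene without a call is therefore not shown to be unchanged.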

Other observations

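Chosen only after the results were seen were the pathway test, the test of scaling, the tests of words outside the 3' UTR and in genes lacking a word, the comparison of word carriers between the siRNAs, the scans of genes that differ between the siRNAs, and the comparison with a control sequence, which was written down from general knowledge once the word was known. Pathway annotations in the deposited table were searched for enrichment among the called genes. Among 104 annotated genes that fell, 13 belonged to cytokine-cytokine receptor interaction where 2.21 were expected of 5940 annotated tested genes (Fisher's exact test, adjusted p = 7.19e-05). They included, named after the values were seen, CCL20, CCL26, CSF2, CXCL8, EBI3, IL1A and the receptor gene NGFR. Also past the test were the rheumatoid arthritis term (7 genes, 0.81 expected, adjusted p = 0.00201) and the IL-17 signaling term (8 genes, 1.52 expected, adjusted p = 0.0133). The arthritis term shared all its genes but TMEM64 with the cytokine term. The IL-17 term shared CCL20, CSF2, CXCL8 and IL1B, and its other genes were NFKBIA, S100A2, S100A14 and S100A16. Genes outside the cytokine term were likewise named after the values were seen. No term passed among the 85 annotated genes that rose, out of 319 terms.

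Among the genes that rose, the most enriched 7-base word was UCGGAGA, in the 3' UTR of 21 of 170 genes where 3.2 were expected, with a family-wise permutation p = 0.001, the smallest that 1000 permutations can give; over all 254 tested carriers the median log2 fold change was 0.14 with either siRNA against 0.03 and 0.01 in other genes. Of the 149 higher genes without it there, 39 carried it elsewhere in a coding transcript where 16.4 were expected (permutation p = 0.0001, the smallest possible). Of the 199 lower genes without it there, 10 carried it elsewhere where 19.7 were expected, while ST3GAL5, which fell, holds it in its 3' UTR. A factor that scales a whole library and remains in the FPKM is argued against. The median log2 change of all tested genes was 0.0137 (spread over genes 0.30), below the smallest change of a called higher gene, 0.70. FPKM is already divided by depth, so a median near 0 was likely from the start. Scaling by the median ratio to the control, chosen after seeing the data, kept 312 of the 373 calls. The word is complementary to positions 2 to 8 of UUCUCCGAACGUGUCACGU, the sense strand of a negative control siRNA in wide use, so a candidate explanation for part of the higher calls is silencing by the control siRNA itself, although the labels do not give its sequence and the site of the antisense strand, UGUCACG, ranked only 1939 of 16384 words (8 higher genes against 4.8 expected; carrier medians 0.05 and 0.02). Among all 170 higher genes, CGGAGAA, CCGGGGG, GGCCACC and AUGGAGA passed as well (family-wise permutation p = 0.004, 0.01, 0.019 and 0.027). Their carrier medians with siRNA1 and siRNA2 were, in that order, 0.116 and 0.083, -0.057 and 0.015, -0.015 and 0.013, and 0.032 and 0.025. CGGAGAA overlaps UCGGAGA and is complementary to the first 7 bases of the same sense strand, so its pass is not separate from that of UCGGAGA. The scan matched genes on 3' UTR length and not on base composition. In higher genes that lack UCGGAGA in the 3' UTR no other word passed (family-wise permutation p = 0.059). Silencing through other words thus cannot be told apart there. A response to DLX5 loss stays open for these genes and is not excluded for carriers of UCGGAGA.

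Among the genes that fell, the most enriched word was ACUCAGU, in the 3' UTR of 44 of 201 genes where 20.1 were expected (family-wise permutation p = 0.002), among them KRT6B, EGFR, AXL and CLDN1. DLX5 transcripts contain it, and called carriers lay lower with siRNA2 than with siRNA1, by a median of -0.11 against 0.02 for the other 157 (permutation p = 0.0028), so silencing by the seed of siRNA2 may add to these calls. Whether siRNA1 acts on the word as well cannot be told apart, as the median of all carriers was -0.06 with siRNA1 and -0.11 with siRNA2 against 0.04 and 0.03 in other genes. In lower genes without the word no other passed (family-wise permutation p = 0.29), which leaves other words open, and the effect of DLX5 loss stays open for them and for PLAU, SERPINB2, KRT14 and KRT16, whose 3' UTRs lack it. A control library that is itself out of place cannot be told apart from a knockdown effect with 1 control.

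The lower DLX1, DLX2 and DLX3 values were weighed against cross-reaction with DLX5. Reads of DLX5 counted for its paralogs are argued against, since 0% of their 31-base words occur in DLX5. DLX1 and DLX2 share at most 14 bases in a row with DLX5, short of the 19 that a full siRNA match needs. DLX3 shares 20, and this stretch holds none of the words enriched between the siRNAs or among the lower genes, which speaks against a match by both siRNAs if those words are their seeds; as the labels do not give the sequences, a match to DLX3 cannot be told apart. Regulation of these genes by DLX5 stays open as a hypothesis and was not tested.

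The siRNA samples also differed from each other by sequence. Of the 200 genes lowest with siRNA1 relative to siRNA2, 78 carried UCAAUCA in the 3' UTR where 16.6 were expected, and of the 200 lowest with siRNA2 relative to siRNA1, 63 carried CUCAGUA where 24.8 were expected (family-wise permutation p = 0.001 for both, the smallest possible). Both words occur in DLX5 transcripts, which hold 9.57% of all words of 7 bases. CUCAGUA overlaps ACUCAGU, the word most enriched among the called lower genes. ACUCAGU was itself enriched in the 200 genes lowest with siRNA2 relative to siRNA1, in 55 where 27.5 were expected (family-wise permutation p = 0.001).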
